A study of Arabidopsis thaliana with 4 samples.

How the data were processed

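Chromatin isolation by RNA purification followed by sequencing (ChIRP-seq) recovers the DNA that lies close to a chosen RNA in crosslinked chromatin, using biotinylated oligonucleotides complementary to that RNA. Here the RNA was APOLO, a long noncoding RNA of Arabidopsis thaliana. Per the labels' protocols, the plants were Col-0 transformed with the full-length APOLO region under the 35S promoter, grown in long days on solid medium, and libraries were made with the NEBNext Ultra DNA kit. The 4 libraries fell into 3 groups by the probes used. ODD and EVEN are separate probe sets against APOLO, and LACZ probes are the control. ODD had 2 libraries (ODD 1 and ODD 2), EVEN had 1 (EVEN 1) and LACZ had 1 (LACZ 1).

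For each library the authors deposited 1 list of peaks on the TAIR10 assembly, and no list pooled libraries. Per the submitters' processing notes the tools were CASAVA 1.8.2, Trimmomatic, Bowtie2 and MACS2, with no version given for the last 3. Peak calling options and the use of a control library in peak calling are not given in the sources used here. Per the file headers, each peak carries its limits, its summit, a pileup signal at the summit, a fold enrichment of that pileup over the local background, and the −log10 of its p-value and q-value. All of these are the authors' values, made within 1 library. They were used to describe, rank or filter peaks within a list, because a fold depends on the depth of its own library. One test in the closing section is the exception and sets folds of the ODD lists against the lowest fold called in EVEN 1. Every deposited peak had a q-value of at most 0.05. The number and width of peaks in such lists depend on depth, enrichment and calling settings together, so lists were compared by overlap and not by length.

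Read totals were not used here, and the depth of each library is therefore known only in relative terms. MACS2 adds 1 to the pileup and to the background before it divides them. The pileup plus 1, divided by the fold, minus 1, therefore returns the local background, and its lowest value in a list follows depth multiplied by fragment length. That lowest background was 1.11 fragments in ODD 1, 2.81 in EVEN 1, 6.23 in LACZ 1 and 6.55 in ODD 2. The shortest peak was 47, 54, 200 and 94 bp in the same order, which points to unequal fragment lengths in peak calling. Dividing the background by the shortest length gave relative fragment numbers of 1 for ODD 1, 2.19 for EVEN 1, 1.31 for LACZ 1 and 2.94 for ODD 2.

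Peaks on the 5 nuclear chromosomes entered the comparisons, and peaks of the mitochondrial and plastid genomes were counted apart. A pair of peaks was shared when they overlapped by at least 1 bp. The chance of sharing was measured with 1000 random placements of the first list, each peak staying on its chromosome, with 0.000999 as the smallest p possible. Random placement ignores repeats and mappability, so a ratio above 1 holds for any feature common to all libraries, and the LACZ list was therefore put through the same comparison. A candidate region was defined as an ODD 1 peak that shared sequence with an EVEN 1 peak and with no LACZ 1 peak. ODD 2 was kept out of that definition and served to look for the same regions in a second ODD library. Shares are given with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. EVEN and LACZ had 1 library each, and a peak list gives no value where its library has no peak, so no test across replicates was run. All p-values describe these libraries, since peaks and genes are not replicates. Comparisons of shares used Fisher's exact test, two-sided, and an exact binomial test for discordant peaks.

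Gene names, biotypes and gene bodies came from a RefSeq gene table of the TAIR10.1 assembly. None of its coordinates are printed. Its fit to the files' positions was checked with the peaks themselves. The share of summits within 200 bp of the edge of a protein-coding gene was lowest at a shift of 0 bp in 10 of 10 chromosome parts, the lower and the upper part of each chromosome, with shifts tested up to 3000 bp in steps of 50 bp. The table gave neither strand nor exons, so the planned 1 kb upstream window became 1 kb on either side of a gene, and exons, introns and untranslated regions were not told apart. The planned searches for the GAAGAA motif and for sequence similarity to APOLO need the genome sequence and were not run. Summits of candidate regions were compared with those of LACZ 1 peaks and with 100000 random positions, with Benjamini-Hochberg adjustment over the 8 tests. Pericentromeres were taken as 3 Mb on either side of the stretch poorest in protein-coding genes on each chromosome.

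The 12 gene lists were fixed before the data were examined, and so were the alternatives unless stated otherwise. Of 197 loci named in them, 197 were found in the table. The SAUR and GH3 families were taken by symbol or synonym. For each list, the number of genes with a candidate region in the gene body or within 1 kb was compared with 10000 random lists of the same size matched on gene length in 10 bins. That test was one-sided, with Benjamini-Hochberg adjustment over the lists. Genes were named by a rule with 3 parts. It took APOLO, PID, WAG2 and AZG2 whatever their values. It took the 20 candidate regions also present in ODD 2 whose poorer rank by fold enrichment, of the ranks in ODD 1 and EVEN 1, was best. It took up to 4 members of best rank from each gene list.

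Alternatives covered a stricter q threshold (−log10 q of at least 5), an overlap of at least 50% of the shorter peak, lists cut to equal length, ODD 2 in place of ODD 1, pericentromeres left out, 3 other rules for LACZ or ODD 2, other gene windows and merging of peaks within 200 bp. After seeing the data, 200 bp windows on the summits with lists cut to equal length, and removal of a mitochondrial copy on chromosome 2, were added. The overlap code was tested on simulated data. A planted overlap of 20.0% of 16126 peaks was recovered as 20.1%, and the ratio with nothing planted was 1.02. Random lists of 40 genes were called in 5% of cases at an unadjusted p under 0.05. Lists of 40 built with a fixed, doubled number of hits were called in 100%. That share does not measure the power for shorter lists or after adjustment. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.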

Results

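APOLO ChIRP-seq libraries were compared to ask which parts of the Arabidopsis genome were recovered with 2 separate sets of probes against the APOLO long noncoding RNA and not with control probes. The plants overexpressed APOLO. The ODD probe set was used in 2 libraries, and the EVEN set and the LACZ control probes in 1 library each, so most values have no replicate. The lists held 16126 nuclear peaks in ODD 1, 20470 in EVEN 1, 12546 in LACZ 1 and 58146 in ODD 2. They covered 2.01, 2.32, 3.80 and 13.0 Mb in that order, with median peak widths of 103, 92, 269 and 181 bp. Depth is known only in relative terms: set to 1 in ODD 1, the estimated number of fragments was 2.19 in EVEN 1, 1.31 in LACZ 1 and 2.94 in ODD 2. The order of the lists depended on the threshold. With −log10 q of at least 5, EVEN 1 kept 3545 peaks, fewer than the 8197 of ODD 1 and the 4456 of LACZ 1, and ODD 2 kept 39423. Fold enrichments given for peaks are the authors', over the local background of the library.

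The APOLO gene itself (AT2G34655) held one of the widest peaks in each APOLO-probe library and none with the control probes. On TAIR10 chromosome 2 the ODD 1 peak spanned 14596650 to 14597580, with a fold enrichment of 16.6 and a −log10 q of 70.8. It was 931 bp wide, the fourth widest of the ODD 1 list. The EVEN 1 peak spanned 14596715 to 14597538 with a fold of 14.1 and was also the fourth widest of its list. The ODD 2 peak spanned 14596617 to 14597674 with a fold of 12.4, and its width of 1058 bp ranked 80 among 58146 nuclear peaks. The gene table lists this locus as protein-coding. Probes complementary to APOLO can also bind the APOLO DNA and the transgene directly, and the lists do not tell the RNA from the DNA as the target. APOLO ranked second of the 2706 candidate regions that were also present in ODD 2.

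PID, WAG2 and AZG2 had been fixed for inspection because they are reported targets of APOLO. PID (AT2G34650), the neighbour of APOLO, encodes PINOID, a protein kinase that acts on PIN auxin transporters. No ODD 1 peak lay in PID or within 1 kb of it. EVEN 1 had 3 peaks there, with folds of 3.68, 3.68 and 3.94, and ODD 2 had 5, with folds from 2.73 to 3.58. LACZ 1 had none. At WAG2 (AT3G14370), a kinase gene related to PID, an ODD 1 peak at 4799414 to 4799569 of chromosome 3 with a fold of 4.73 overlapped an EVEN 1 peak at 4799339 to 4799457 with a fold of 3.41. The ODD 2 peak over it was wider, at 4798992 to 4799645, with a fold of 10.3, and LACZ 1 had no peak. At AZG2 (AT5G50300), which encodes a purine and cytokinin transporter, the ODD 1 peak at 20466301 to 20466524 of chromosome 5 had a fold of 8.86. The overlapping EVEN 1 peak at 20466272 to 20466502 had a fold of 4.60, and the overlapping ODD 2 peak at 20466264 to 20467067 a fold of 12.4. A LACZ 1 peak with a fold of 2.76 also lay in AZG2, at 20466625 to 20466880. It did not touch the ODD 1 peak, but it overlapped the wider ODD 2 peak. Another of the 4 EVEN 1 peaks at AZG2, at 20466785 to 20466838 with a fold of 3.68, lay inside this LACZ 1 peak.

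**Figure D1:**
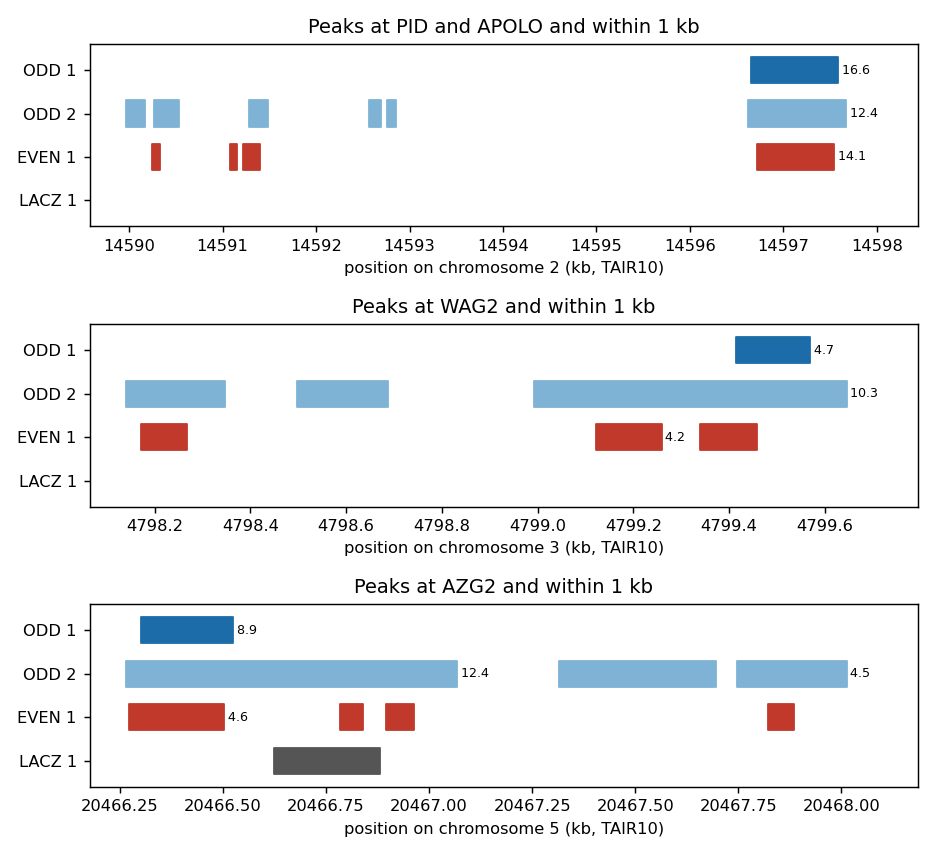
Peaks of the 4 libraries (rows) at PID and APOLO, at WAG2 and at AZG2, with 1 kb on either side, drawn to scale along the chromosome (x axes, kb, TAIR10); numbers beside bars are fold enrichments. APOLO holds a wide peak in the 3 APOLO-probe libraries with folds of 16.6, 12.4 and 14.1 and none in LACZ 1, while AZG2 also holds a LACZ 1 peak.

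Peaks of the 2 probe sets coincided more often than random placement gives, and so did peaks of either set with the control. ODD 1 peaks coincided with EVEN 1 more than with LACZ 1. For EVEN 1 peaks, 59.5% overlapped ODD 2 against 16.2% at random, a ratio of 3.67. Their overlap with LACZ 1 was 18.6% against 4.37%, a ratio of 4.26. A high random share limits the ratio that the long ODD 2 list can reach. It does not by itself account for the value of 3.67, since ODD 1 with ODD 2 reached 5.69 at a random share of 16.7%. Counted over ODD 2 peaks, the ratio was 3.47 with EVEN 1 and 2.37 with LACZ 1. Counted over LACZ 1 peaks, the ratio with EVEN 1 was 3.94, so EVEN 1 was no closer to ODD 2 than to the control by these ratios. Of the ODD 1 peaks, 24.0% (95% interval 23.4 to 24.7) overlapped an EVEN 1 peak, against 3.99% at random, a ratio of 6.01. The overlap with LACZ 1 was 13.4% (12.9 to 13.9) against 4.48%, a ratio of 2.99. Each p was 0.000999, the smallest that the placements can give. Among the 3860 ODD 1 peaks shared with only one of EVEN 1 and LACZ 1, 72.2% (70.7 to 73.6) were shared with EVEN 1 (exact binomial test, two-sided, p = 8.01e-173). Of the EVEN 1 peaks, 19.1% overlapped ODD 1 and 18.6% overlapped LACZ 1, the former with a ratio over random of 6.02. The ratio for ODD and EVEN depended on the lists: it was 15.8 with −log10 q of at least 5, and 3.47 with ODD 2 in place of ODD 1.

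**Figure D2:**
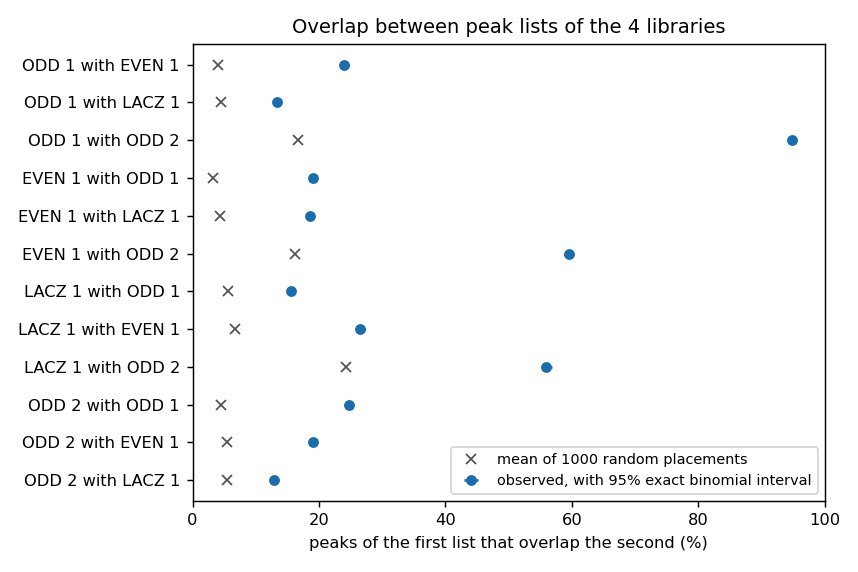
Percent of peaks of the first library that overlap a peak of the second (x axis) for the 12 ordered pairs of the 4 libraries (y axis); points are observed shares with exact 95% binomial intervals and crosses the mean of 1000 random placements. The 12 observed shares lie above their crosses, from 13.0% for ODD 2 with LACZ 1 to 94.8% for ODD 1 with ODD 2.

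The 2 ODD libraries shared nearly all of the shorter list. Of the ODD 1 peaks, 94.8% (94.5 to 95.2) overlapped an ODD 2 peak, against 16.7% at random, and 24.7% of the ODD 2 peaks overlapped an ODD 1 peak. Agreement rose with fold enrichment. In the 1612 ODD 1 peaks of highest fold, the first of 10 equal parts, 99.9% were in ODD 2, 48.4% (45.9 to 50.9) in EVEN 1 and 25.9% (23.8 to 28.1) in LACZ 1. In the last part the shares were 84.7%, 13.0% and 10.4%. In the first of 10 parts of ODD 2, 87.3% of peaks were in ODD 1, 31.6% in EVEN 1 and 15.5% in LACZ 1. A majority of ODD 1 peaks, 10508 or 65.2%, were present in ODD 2 and had neither an EVEN 1 nor a LACZ 1 peak.

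**Figure D3:**
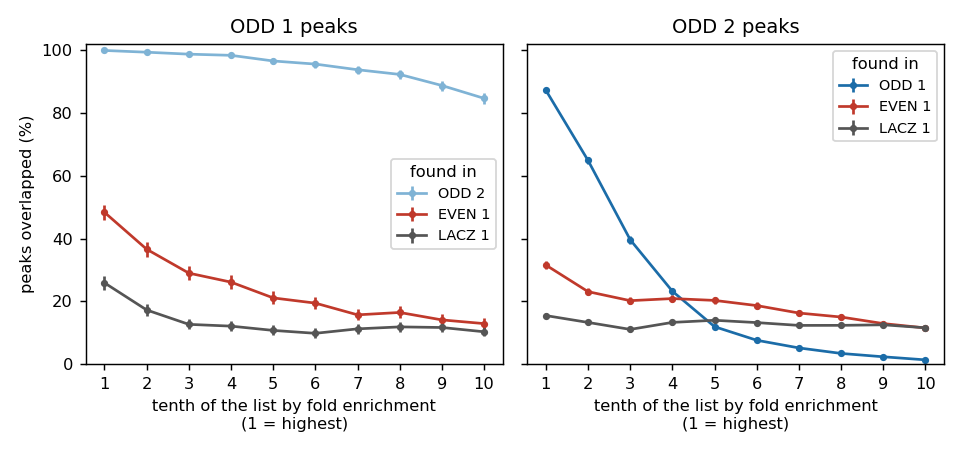
Percent of ODD 1 peaks (left) and ODD 2 peaks (right) that overlap a peak of each other library (y axis), by each of 10 equal parts of the list ordered by fold enrichment (x axis, part 1 is the highest); bars are exact 95% binomial intervals. The share of ODD 2 peaks found in ODD 1 falls from 87.3% to 1.41%, while the share found in LACZ 1 goes from 15.5% to 11.6%.

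Candidate regions, held by ODD 1 and EVEN 1 and not by LACZ 1, numbered 2786, or 17.3% of the ODD 1 peaks. They formed 2747 merged regions covering 558 kb, with a median width of 187 bp. Within 1 kb or inside the gene body, they touched 3064 of 27444 nuclear protein-coding genes (11.2%). A further 1087 ODD 1 peaks were shared with both EVEN 1 and LACZ 1. In ODD 2, 2706 of the candidate regions (97.1%, 96.4 to 97.7) were found again. The share was 94.0% for ODD 1 peaks with neither an EVEN 1 nor a LACZ 1 peak (odds ratio 2.16, Fisher's exact test, p = 3.63e-12) and 96.1% for ODD 1 peaks with a LACZ 1 peak (odds ratio 1.37, p = 0.0544). The last group combined 98.3% (97.3 to 98.9) for peaks shared with both EVEN 1 and LACZ 1 and 93.9% (92.4 to 95.3) for peaks shared with LACZ 1 alone. The difference from peaks with neither was smaller at like fold enrichment and depended on the threshold. Within 10 classes of fold enrichment the odds ratio was 1.42 (Mantel-Haenszel), and candidate regions had the higher share in 4 of 10 classes, those of lowest fold, up to 93.6% against 83.5%. The shares were equal at 100% in the class of highest fold. In the classes between, candidate regions had the lower share, for example 95.3% against 96.9%. With −log10 q of at least 5 the difference over all classes turned, to 96.9% against 98.5%. With 200 bp summit windows and lists cut to equal length it vanished, at 68.7% against 68.9%. The number of regions was 830 with −log10 q of at least 5 and 8260 with ODD 2 in place of ODD 1.

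The 20 candidate regions of best rank had folds of 13.0 to 18.9 in ODD 1, 7.09 to 14.8 in EVEN 1 and 6.23 to 16.5 in ODD 2. Their summits lay inside protein-coding genes in 11 cases, inside other genes in 5, and within 1 kb of a gene in 4. After APOLO, the widest were AT4G02885, an RNA gene without a coding sequence (chromosome 4, 6664476 to 6665142, ODD 1 fold 13.8), and AT5G25756 (chromosome 5, 8962053 to 8962570, ODD 1 fold 17.9, EVEN 1 fold 10.2). Regions inside protein-coding genes included AT1G56670 (chromosome 1, 21241979 to 21242426, ODD 1 fold 17.7) and AT1G71870 (chromosome 1, 27034019 to 27034437, 14.6). AT2G21560 (chromosome 2, 9230579 to 9230974) had an ODD 1 fold of 16.4, and AT5G14540 (chromosome 5, 4687800 to 4688086) one of 13.3. G3Pp5 (AT2G13100), named as a glycerol-3-phosphate permease, held a region at 5390546 to 5390886 of chromosome 2 with an ODD 1 fold of 14.1. ARI5 (AT1G05890), of the ARIADNE family of ubiquitin ligases, held one at 1779611 to 1779933 of chromosome 1 with a fold of 15.2. KCS12 (AT2G28630), a 3-ketoacyl-CoA synthase of the family that elongates very long chain fatty acids, held one at 12276970 to 12277189 of chromosome 2 with a fold of 14.2.

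Within 1 kb of AT5G42190, which encodes the SKP1-like protein ASK2 of ubiquitin ligase complexes, the region at 16856111 to 16856413 of chromosome 5 had an ODD 1 fold of 18.4 and an EVEN 1 fold of 7.09. Regions within 1 kb also stood at AT3G42150 (ODD 1 fold 15.6), the lncRNA gene AT2G08465 (14.1) and the pseudogene AT5G49465 (15.2). The lncRNA gene AT1G05817 held a region with folds of 13.0 in ODD 1 and 12.3 in EVEN 1, and the pseudogenes AT5G26283 and AT4G06712 held regions with ODD 1 folds of 15.2 and 15.5. The first of the 20, at AT2G07648 (chromosome 2, 3431521 to 3431601, ODD 1 fold 18.9), and those at AT2G07667 and AT2G07677 (15.3 and 14.9) lie in the copy of the mitochondrial genome on chromosome 2. They were 71 to 81 bp wide. Of the 20 regions, 9 lay in pericentromeres. Of the 100 of best rank, 41% did (31.3 to 51.3), against 25.0% (23.4 to 26.7) of all candidate regions and 25.2% of chromosome length. Of those 100, 10 lay in the mitochondrial copy, which is itself pericentromeric; without it the share was 34.4% (24.7 to 45.2) of 90, against 23.4% (21.8 to 25.0) of all candidate regions.

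Candidate summits lay mostly in protein-coding genes, as did the summits of the control list. The share was 74.8% (73.1 to 76.4) for candidate regions, 72.3% (71.6 to 73.1) for LACZ 1 and 53.9% for random positions. The odds ratio was 1.14 against LACZ 1 (Fisher's exact test, adjusted p = 0.0112) and 2.54 against random positions (adjusted p = 1.07e-110). Other genes, such as pseudogenes and RNA genes, held 8.90% of candidate summits and 14.4% of LACZ 1 summits (odds ratio 0.580, Fisher's exact test, adjusted p = 1.70e-15). Positions outside genes but within 1 kb held 10.8% of candidate summits, 8.54% of LACZ 1 summits (odds ratio 1.29, Fisher's exact test, adjusted p = 0.000443) and 25.0% of random positions. Positions farther away held 5.53%, 4.69% (exact test, adjusted p = 0.0637) and 11.1%. The lower share in other genes was not particular to candidate regions, since it was 9.34% in ODD 1, 10.1% in EVEN 1 and 10.8% in ODD 2. In protein-coding genes the candidate share lay between those of ODD 1 (71.9%) and EVEN 1 (77.5%). Within 1 kb of a gene it also lay between the 2 lists, at 13.2% and 8.10%. The difference from LACZ 1 in protein-coding genes was lost in the chromosome arms, at 87.8% against 87.3% (exact p = 0.558). It turned with −log10 q of at least 5, at 61.6% against 65.9% (exact p = 0.0172).

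**Figure D4:**
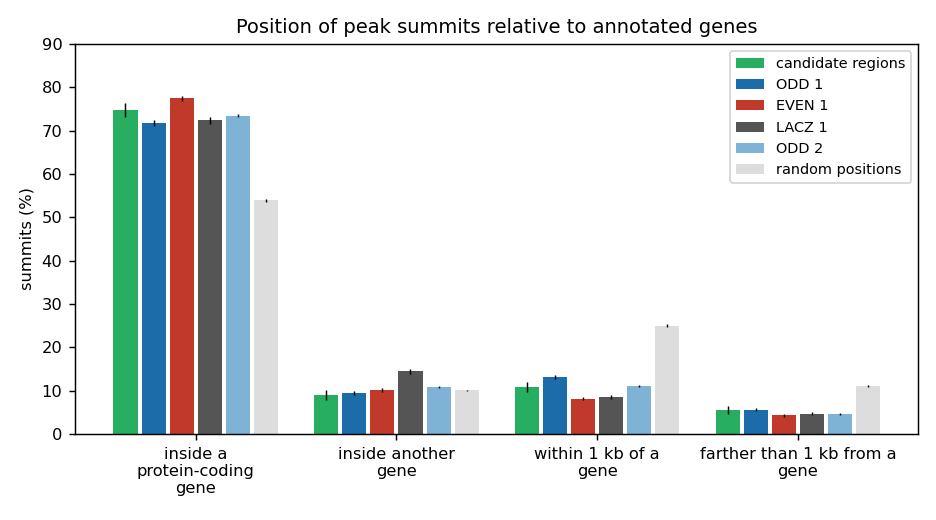
Percent of peak summits (y axis) in 4 classes of position relative to annotated genes (x axis) for candidate regions, the 4 libraries and 100000 random positions; bars carry exact 95% binomial intervals. Candidate regions (74.8%) and LACZ 1 peaks (72.3%) both exceed random positions (53.9%) in protein-coding genes.

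None of the 12 fixed gene lists held more candidate regions than length-matched random lists after adjustment, and 2 had an unadjusted p under 0.05. The list of APOLO, its neighbour and reported targets had regions at 3 of 4 genes against 0.442 expected (permutation p = 0.0047, adjusted p = 0.0564). Its members are known from the study of APOLO itself, so it is not independent evidence. The 3 genes were AZG2, WAG2 and APOLO, whose own DNA the probes can bind directly. The list was not tested without APOLO. DNA methylation genes had regions at 5 of 15 against 1.98 expected (permutation p = 0.0368, adjusted p = 0.221). They were RDR2, an RNA-dependent RNA polymerase of small RNA-directed DNA methylation (chromosome 4, 6784941 to 6785246, ODD 1 fold 12.3, EVEN 1 fold 4.70), the chromomethylase gene CMT3 (7.09 and 4.73), AGO4 (6.14 and 3.89), the DNA demethylase gene ROS1 (6.45 and 3.16) and, outside the naming rule and added to complete the count, DDM1 (6.05 and 2.97). In LACZ 1, 11 of these 15 genes had a peak against 8.21 expected (permutation p = 0.113), and 0 of the 12 lists passed. The DNA methylation list passed adjustment in no alternative. Its lowest adjusted p was 0.163 (permutation test), with lists cut to equal length and 4 of 15 genes against 1.19 expected. The count was 6 against 5.72 with ODD 2 in place of ODD 1, and 3 against 1.69 with no LACZ 1 peak within 500 bp.

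Auxin signalling genes had regions at 8 of 50, against 5.82 expected (permutation p = 0.217). The strongest was IAA2, an Aux/IAA repressor gene, at 8181572 to 8181769 of chromosome 3 with folds of 10.9 in ODD 1, 8.07 in EVEN 1 and 13.4 in ODD 2. IAA28, IAA26 and the auxin response factor gene ARF3 followed, with ODD 1 folds of 8.36, 5.67 and 4.69. Auxin transport genes had 3 of 22 against 2.77 expected (permutation p = 0.536), which were the kinase genes WAG1 and WAG2 (ODD 1 fold 4.73 at each) and the efflux carrier gene PIN7 (3.34). The PIN7 peak was among the weakest of the ODD 1 list, ranking at 95.4% from the highest fold. Auxin synthesis had 2 of 14 against 1.64 (permutation p = 0.503), the flavin monooxygenase genes YUC2 and YUC1, with ODD 1 folds of 5.67 and 4.26. The SAUR and GH3 families of early auxin response had 6 of 90 against 8.22 (permutation p = 0.838). Among them AT4G34750 (SAUR49), AT1G29420 (SAUR61), AT2G24400 (SAUR38) and AT4G38860 (SAUR16) had ODD 1 folds of 12.0, 16.5, 4.71 and 4.73, and the last had no ODD 2 peak. Their EVEN 1 folds were lower, at 4.26, 3.68, 3.39 and 3.28 in the same order.

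Cytokinin genes had regions at 4 of 25 against 3.06 expected (permutation p = 0.372). They were AZG2, the receptor gene AHK4 (ODD 1 fold 6.24) and the response regulator genes ARR9 (5.67) and ARR6 (6.13). Root development genes had 3 of 21 against 2.42 (permutation p = 0.444), the root patterning gene SHR (5.96), the root hair gene RHD6 (5.20) and LBD33 (3.26). The LBD33 peak ranked at 97.1% of the ODD 1 list from the highest fold. Polycomb components had 0 of 11 against 1.42 (permutation p = 1), and Polycomb target genes 1 of 10 against 1.25 (permutation p = 0.738), the floral gene AP3 with an ODD 1 fold of 4.44. The lists of highly transcribed genes gave 2 of 19 against 1.97 for photosynthesis (permutation p = 0.596), at the light-harvesting genes LHCA3 (8.61) and LHCB3 (3.92). Housekeeping genes gave 2 of 9 against a median of 1 at random (permutation p = 0.303), at EF1A (7.09) and ACT7 (4.89). Adjusted p was 0.795 or more for the lists other than those of APOLO and DNA methylation. The call for the APOLO list was gained with lists cut to equal length (permutation test, adjusted p = 0.0108), without pericentromeres (0.0372), with gene bodies alone (0.0072) and with 200 bp summit windows on lists cut to equal length (0.0264). The list fell to 2 of 4 genes with an overlap of at least 50% (permutation test, adjusted p = 0.537) and with −log10 q of at least 5 (0.0624), where WAG2 was lost, and with no LACZ 1 peak within 500 bp (0.583), where AZG2 was lost. It had 3 of 4 with a window of 2 kb (permutation test, adjusted p = 0.139). With ODD 2 in place of ODD 1, auxin synthesis passed, with 10 of 14 genes against 4.65 expected (permutation test, adjusted p = 0.0468). In that setting the APOLO list, which counts APOLO itself, had 4 of 4 genes against 1.25 expected (permutation test, adjusted p = 0.0546). The AZG2 region described above was lost there, because the wider ODD 2 peak overlapped the LACZ 1 peak. AZG2 counted through another site, an ODD 2 peak at 20467747 to 20468012 with a fold of 4.50. The EVEN 1 peak under it, at 20467821 to 20467885, had a fold of 3.68.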

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

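Of the tests in this part, those on why the EVEN library lacks many ODD peaks were chosen after the result was seen, and the mitochondrial window on chromosome 2 was set after looking at the peaks.

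Mitochondrial peaks stood out because they lie outside the nuclear comparisons and made up a larger share of the APOLO-probe lists numbered 1 than of the control list. They were 0.985% of the ODD 1 peaks (0.839 to 1.15) and 0.928% of the EVEN 1 peaks (0.802 to 1.07), against 0.498% (0.383 to 0.636) of the LACZ 1 peaks and 0.348% of the ODD 2 peaks. Such a share falls as the nuclear list grows: the number of mitochondrial peaks was 161 in ODD 1, 192 in EVEN 1, 63 in LACZ 1 and 203 in ODD 2, and they covered 16.8, 28.6, 35.4 and 49.1 kb.

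The nuclear copy of mitochondrial DNA, the part of chromosome 2 that holds AT2G07648, AT2G07667 and AT2G07677, held 3 of the 20 best-ranked candidate regions. It had 4.69 times the peak density of the rest of the chromosome in ODD 1 and 3.90 times in EVEN 1. Mitochondrial reads placed on their nuclear copy are a candidate source, since LACZ 1, whose probes have no relation to APOLO, also had 2.86 times the density there (2.27 to 3.56). In ODD 2 the density in the copy was 574 peaks per Mb, against 633 in ODD 1, while the rest of the chromosome held 495 per Mb against 135, so its ratio of 1.16 says little for or against this source. The LACZ 1 peaks in the copy also differed in width. The median there was 66 bp in ODD 1, 80 bp in EVEN 1 and 138 bp in ODD 2, against 105, 95 and 180 bp in the rest of the chromosome. In LACZ 1 it was 328 bp against 269 bp. Candidate regions overlap no LACZ 1 peak by definition, so the LACZ 1 density describes the copy and not those regions. No biological explanation was tested.

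The larger pattern is that 65.2% of ODD 1 peaks were present in ODD 2 and had no peak with the EVEN or LACZ probes. Lower depth of EVEN 1 is argued against by its estimated fragment number, which was 2.19 times that of ODD 1. Its lowest fold called at the lowest background was 2.63 against 3.31, a ratio of 1.26 for ODD 1 over EVEN 1. That fold depends on the same background as the fragment number and is not separate evidence. Of 5001 peaks without a LACZ 1 peak and with folds of at least 5.25 in both ODD lists, 71.6% (70.4 to 72.9) had no EVEN 1 peak. The share was 84.3% for the 8213 weaker ones. The limit of 5.25 was set on ODD folds, and EVEN 1 folds at the same sites can be lower. Chance loss near the EVEN 1 calling limit was therefore not tested in either group. DNA bound directly by single probes of the ODD set remains open, since its test needs the probe and genome sequences. Poorer enrichment with the EVEN probes (3545 peaks with −log10 q of at least 5, against 8197 in ODD 1) and a real difference between the parts of APOLO that the probe sets reach are open too and were not tested.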

How the results depend on the processing

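The added setting with 200 bp summit windows on lists cut to equal length (summit windows) was chosen after seeing the data. The excess of ODD and EVEN overlap over random placement (ratio 3.47 to 15.8) and the preference of ODD peaks for EVEN over LACZ (63.8% to 73.7%) held in the 6 alternatives run for them. Candidate regions numbered 830 with −log10 q of at least 5, and 1884 to 3873 in the alternatives that kept ODD 1 and the authors' threshold. That stricter threshold left 8197 nuclear peaks in ODD 1, 3545 in EVEN 1 and 4456 in LACZ 1. Recovery in ODD 2 turned to 96.9% (98.5% for peaks with neither, exact p = 0.00245) at the stricter threshold and did not differ detectably in summit windows, at 68.7% (68.9%, exact p = 0.837). The share of candidate summits in protein-coding genes stood at 72.9% with an overlap of at least 50%, and at 87.8% without pericentromeres, both no longer past the threshold. It turned at the stricter threshold, to 61.6% against 65.9% in LACZ 1 (exact p = 0.0172), and did not differ detectably from the 72.3% of LACZ 1 with equal lists, at 71.8% (exact p = 0.60), or in summit windows, at 71.3% (exact p = 0.304). The number of gene lists called was 1 with equal lists, without pericentromeres, with gene bodies alone and in summit windows. The cause was not tested for these changes. With ODD 2 in place of ODD 1 the values were a ratio of 3.47, an EVEN share of 63.8%, 8260 regions, 36.5% found in ODD 1 (21.4% for peaks with neither), 81.3% in protein-coding genes and 1 list. Without ODD 2, recovery, the overlaps with ODD 2, the share of ODD 1 peaks found in ODD 2 alone and the choice of the 20 best-ranked regions have no value; the overlap of ODD 1 with EVEN 1, the candidate regions, their features and the gene lists do not use it. Of the 49 named genes, 28 kept their candidate region at the stricter threshold, 36 with no LACZ peak within 500 bp, 38 without pericentromeres and 43 with ODD 2 in place of ODD 1. No paired analysis was possible because the groups share only replicate number 1 and peak lists give no model across libraries. The alternatives for the GAAGAA motif and for similarity to APOLO were not run. Depth limits the lists: the absence of a peak in the shallow ODD 1 list, as at PID, is not absence of signal.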

Other observations

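The comparison of symbol families and the description of wide regions were chosen after seeing the data, and the test of the APOLO neighbourhood was fixed before its result was seen. Wide peaks with both probe sets were rare: 10 candidate regions had ODD 1 and EVEN 1 peaks of at least 400 bp. Besides APOLO, AT5G25756, AT4G02885 and AT1G05817, they lay at AT5G37793, AT1G20130, AT4G22505, AT4G15160 and AT1G49490, and within 1 kb of the lncRNA gene AT1G06857. AT4G22505 had an ODD 1 peak of 676 bp with a fold of 11.3 and an EVEN 1 peak of 685 bp with a fold of 9.98, and AT1G20130 had folds of 16.1 and 6.10. Among 48 families of gene symbols, the arabinogalactan proteins (AGP, 7 of 30 genes with a region against 2.70 expected, permutation p = 0.0132) and the early nodulin-like proteins (ENODL, 6 of 22 against 2.06, p = 0.0134) stood highest. Neither passed adjustment (permutation test, adjusted p = 0.322 for both). CIPK, a family of protein kinases, was the third with an unadjusted p under 0.05 (6 of 21 against 2.51, permutation p = 0.0328, adjusted p = 0.525).

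One hypothesis was that APOLO RNA stays near its own locus, so that candidate regions would crowd around it. Within 500 kb of APOLO, itself left out, there were 25 candidate regions (95% Poisson interval 16.2 to 36.9). The median over 1120 positions on the same arm was 25, and their central 95% reached up to 38. Fewer regions were found around 49.2% of the positions. LACZ 1 had 97 peaks in the same window against a median of 98. Crowding on this scale was not seen, and shorter distances were not tested. The plants also carried an APOLO transgene, and the lists do not tell its RNA from RNA made at the native locus. The count therefore cannot decide whether RNA made at the native locus stays near it.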
